A study of Homo sapiens with 6 samples.

How the data were processed

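RNA was profiled in 6 libraries of Ishikawa cells, 3 labelled EV and 3 overexpressing TEFM, as the labels give them; what EV stands for is not stated in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was isolated with oligo(dT) beads and fragmented, cDNA was primed with random primers, and adaptor-ligated fragments were amplified by PCR. Selection with oligo(dT) leaves most transcripts without poly(A) tails out of the libraries. Whether the libraries keep strand is not given in the sources used here, so reads of overlapping and antisense genes may be shared.

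The deposited table holds 61806 genes, 41389 of them with a symbol. Per the file headers and the values, it gives raw whole-number counts and FPKM for each library. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1 and the genome build was hg19; the aligner, the counting tool and its treatment of reads that map to several genes are not given in the sources used here. The coordinates in the table match GRCh38 rather than hg19: of 58254 gene IDs shared with GENCODE v29, 99.98% overlap on the same chromosome and 89.61% share an exact start or end. Coordinates are printed as the table gives them. The deposited FPKM equal the count per kilobase of the deposited exonic gene size and scaled by the library's column total; recomputed values lay within 0.0051 for 100% of genes. Depth ranged from 14252668 to 17891047 counts.

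The design written before the data were examined named limma on log2(FPKM + 1), with edgeR in its place if raw counts were found, and raw counts were found. Genes with a mean FPKM of at least 1 over the 6 libraries were tested (14254). The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts with TMM scaling, two-sided, Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. FPKM levels are described as means and SD over the 3 libraries of a group. TMM factors ranged from 0.982 to 1.02, and the median log2 fold change of all tested genes was -0.00.

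Lists of genes, 26 in all, were fixed before the data were examined: NF-kB targets and pathway, reactive oxygen species enzymes, NRF2 targets, 4 lists of mitochondrial genes, tumour cell processes, signs of handling and library quality, and markers of other cell types. Of their symbols 673 matched by symbol and 19 through another symbol of the same gene ID. The 23 lists with at least 3 tested genes were tested with camera of limma 3.58.1 at the preset correlation of 0.01, and also with an estimated correlation and with fry, with adjustment over the lists. Of these, 9 passed camera with the preset correlation, 1 with an estimated correlation and 20 by fry, which asks whether a list's genes move one way on balance and does not compare them with other genes.

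Genes are named by a rule fixed at the same time. It takes TEFM, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean FPKM of at least 5, a gene symbol and no overlap between groups, up to 4 members of each list with the smallest p, the 3 genes with the smallest p and the 5 with the highest mean FPKM. Other list members may be given by value.

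The libraries were compared before they were averaged. Chi-square per degree of freedom was 2.17 to 4.78 within groups and 26.1 to 34.2 between groups, so libraries of a group differed by more than sampling noise, and groups by far more. The test was run on simulated data drawn from the means and library sizes of these libraries, with 200 changed genes; 5.26% of its calls were false. Alternatives covered scaling, filters on low values, pseudocounts, robust and untrended fits, quantile normalisation, DESeq2 1.42.0, a replicate block and each library left out in turn. GC and length offsets and the removal of shifted chromosome segments were added after seeing the data. GC content came from GENCODE v29 transcripts and was known for 98.6% of tested genes. Chromosome segments were 10 Mb bins with at least 15 tested genes, called shifted when the median lay at least 0.25 from 0 and had an adjusted p under 0.05 against 10000 random gene sets of the same size.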

Results

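Gene expression was measured by RNA-seq of poly(A)-selected RNA from Ishikawa cells, an established human endometrial adenocarcinoma cell line. The 6 libraries comprised 3 labelled EV and 3 from derivatives that overexpress TEFM, the mitochondrial transcription elongation factor. The submitters describe the replicates as independent and biological. The p-values below measure the spread between libraries of a group, for which edgeR put the common biological coefficient of variation at 4.81%. Where libraries of a group share a derivation, these p-values do not cover variation between derivations. The title of the series raises the question whether TEFM acts in endometrial carcinoma through reactive oxygen species and NF-kB signalling. The EV libraries held 17891047, 15092555 and 16053069 counts, and the TEFM libraries 16898807, 17562807 and 14252668. A mean FPKM of at least 1 over the 6 libraries was reached by 14254 genes, which took 98.7% to 98.8% of the counts of each library. Values below are mean FPKM ± SD with n = 3 libraries per group, and log2 fold changes are TEFM minus EV with their standard errors. Counts were also simulated for the TEFM versus EV comparison over the same 14254 genes. There edgeR recovered 19 of 50 genes changed 1.2-fold, 33 of 50 changed 1.5-fold and 44 of 50 changed 2-fold. The simulation changed 50 genes at each fold, while 6184 genes were called in the data. Benjamini-Hochberg adjustment sets a stricter cutoff when fewer genes change, so these shares do not give the recovery in the data.

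TEFM RNA was 5.6-fold higher in the TEFM libraries. The gene (ENSG00000172171, chromosome 17, 30897336 to 30906238, minus strand) stood at 4.31 ± 0.218 FPKM in EV and 23.5 ± 0.653 FPKM in TEFM, n = 3 each. Its counts were 195, 169 and 193 in the EV libraries and 1056, 1054 and 903 in the TEFM libraries. The log2 fold change was 2.48 with a standard error of 0.0788 (edgeR adjusted p = 9.76e-18). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. Gene-level counts do not separate transcripts of an introduced copy from those of the endogenous gene.

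Across the transcriptome, the lists of the integrated stress response and of cholesterol synthesis were lower in the TEFM libraries at the preset correlation of camera. The lists of epithelial adhesion, of immediate early and heat shock genes, of hypoxia and glycolysis, and of mitochondrial and nuclear genes of the respiratory chain were higher. Of these lists, only epithelial adhesion passed also with an estimated correlation. PSAT1, an enzyme of serine synthesis, fell from 246 ± 14.4 to 108 ± 5.40 FPKM, and INSIG1, a regulator of sterol synthesis, from 60.1 ± 3.05 to 26.1 ± 1.64 FPKM. CLDN1, a tight junction protein, rose from 30.4 ± 0.909 to 102 ± 2.49 FPKM, and SLC2A1, a glucose transporter, from 39.9 ± 1.62 to 119 ± 3.37 FPKM. The first principal component, with 58.4% of the variance, parted the 2 groups.

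**Figure D1:**
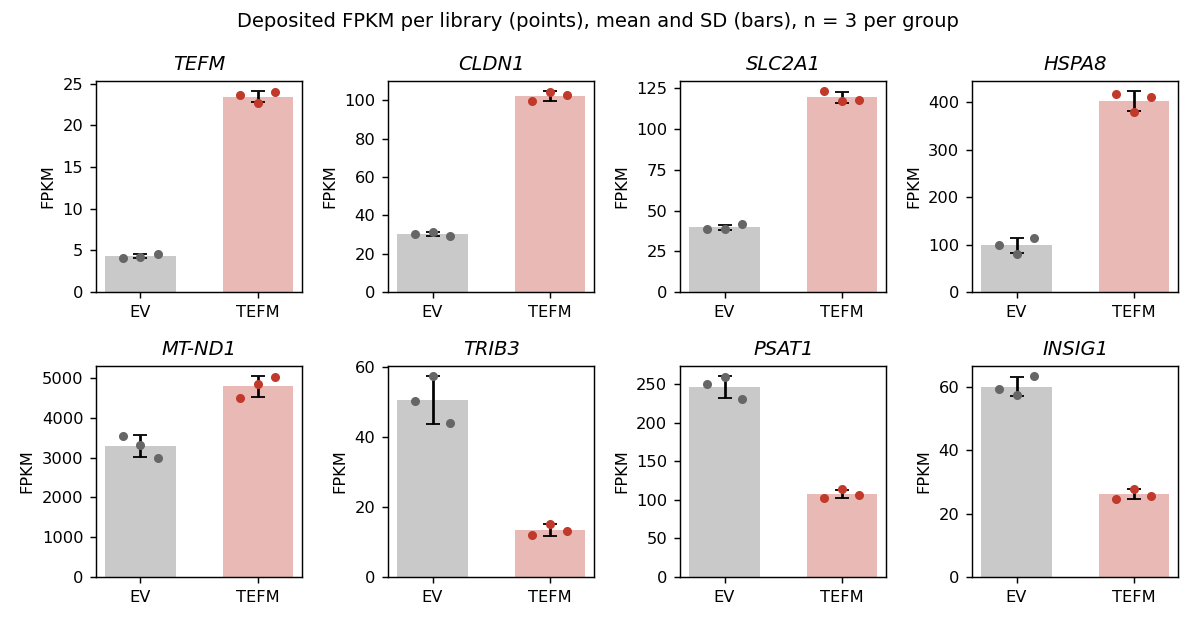
Deposited FPKM (vertical axes, each starting at 0) of 8 genes in the 3 EV and 3 TEFM libraries, with points for libraries, bars for means and error bars for SD. TEFM, CLDN1, SLC2A1, HSPA8 and MT-ND1 were higher in each TEFM library than in each EV library, and TRIB3, PSAT1 and INSIG1 were lower.

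With edgeR's quasi-likelihood test, 6184 of the 14254 tested genes (43.4%) passed an adjusted p of 0.05, 3092 higher and 3092 lower in TEFM. The balance depended on the scaling: 2581 were higher and 3678 lower without composition scaling, 3281 and 2876 with upper-quartile scaling, and 3114 and 3070 with median-of-ratios scaling. With limma on log2(FPKM + 1), which changes the test and its input too, 2186 were higher and 3105 lower. Most changes were small: 4387 of the called genes had an absolute log2 fold change under 0.5, and the median over called genes was 0.34. An absolute log2 fold change of at least 1 was reached by 270 higher and 225 lower genes. The 3 EV and the 3 TEFM values did not overlap for 51.6% of the tested genes, where chance gives 10%. The number with an absolute log2 fold change of at least 1 was 1409 without a filter on low values, 130 at a mean FPKM of at least 5, and 256 with limma on log2(FPKM + 1).

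Among genes with a mean FPKM of at least 5, ZNF114, a zinc finger gene (ENSG00000178150, chromosome 19, 48270081 to 48287608), had the largest rise. It went from 0.647 ± 0.133 to 24.0 ± 1.11 FPKM, a log2 fold change of 5.25 with a standard error of 0.112. ARRB1, which encodes a beta-arrestin (ENSG00000137486, chromosome 11, 75260122 to 75351705), rose from 4.50 ± 0.157 to 25.6 ± 1.80 FPKM. HSPA8, the constitutive heat shock cognate chaperone, rose from 98.5 ± 16.6 to 403 ± 20.7 FPKM, and HSPA1B, an inducible chaperone, from 6.70 ± 0.993 to 33.7 ± 0.783 FPKM. HSPA1B shares nearly its whole sequence with HSPA1A (log2 fold change 0.87), so the split of reads between the pair is uncertain. SYT13, IER5 and COX7B2 rose with log2 fold changes of 2.02, 1.9 and 1.88. The small nucleolar RNA gene SNORD14E rose by a log2 fold change of 2.45 with a standard error of 0.516, but it lies within HSPA8, whose reads it can share.

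Among genes with a mean FPKM of at least 5, the largest falls were in VCX3A, a member of a family of near-identical X-linked genes whose reads cannot be assigned with certainty (17.7 ± 1.71 to 1.91 ± 0.412 FPKM), and in GJA1. GJA1, a gap junction connexin gene (chromosome 6, start 121435595), fell from 19.8 ± 1.46 to 3.68 ± 0.285 FPKM. ADGRL2, an adhesion receptor gene (ENSG00000117114, chromosome 1, 81306147 to 81993932), fell from 12.4 ± 0.133 to 2.5 ± 0.0757 FPKM and had the smallest p of all genes (edgeR adjusted p = 6.97e-22). ARRB1 and ZNF114 followed it, both with an edgeR adjusted p of 3.34e-21. TRIB3, INHBE, CHAC1 and PCK2 fell with log2 fold changes of -1.87, -1.83, -1.70 and -1.63. AMIGO2 and COL9A3 fell with log2 fold changes of -1.80 and -1.65. The processed pseudogene ISCA1P4 fell by a log2 fold change of -1.95 with a standard error of 0.434, from 15.5 ± 8.06 FPKM, the widest EV spread relative to its mean in this group.

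Target genes of NF-kB, the transcription factor named in the series title, moved both ways. Of the 26 tested members, 13 rose, 6 fell and 7 did not pass; adjusted over the list alone, 15 rose and 6 fell. TNFAIP2 rose from 21.0 ± 0.854 to 35.5 ± 1.2 FPKM, NFKB2 from 5.51 ± 0.335 to 8.07 ± 0.224 FPKM and the chemokine gene CXCL10 from 7.42 ± 0.900 to 14.9 ± 1.97 FPKM. PTGS2, which encodes an inducible cyclooxygenase, fell from 6.0 ± 0.159 to 1.67 ± 0.446 FPKM, and CFLAR fell by a log2 fold change of -0.56. TNFAIP3 (log2 fold change 0.28, edgeR adjusted p = 0.0775) and CXCL8 (-0.18, edgeR adjusted p = 0.381) did not pass. The list as a whole had a median log2 fold change of 0.30 and did not pass camera (adjusted p = 0.230; adjusted p = 0.593 with an estimated correlation). Over the 9 members with a mean FPKM of at least 5 its camera adjusted p was 0.0467.

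Among components of the NF-kB pathway itself, 4 of 23 tested rose, 8 fell and 11 did not pass; adjusted over the list alone, 6 rose and 8 fell. LTBR (log2 fold change 0.23) and RELA (0.19) rose, whereas IRAK4 (-0.34), TAB2 (-0.22) and TRAF5 (-0.43) fell. RELA lies on chromosome 11 between 60 and 70 Mb, where the median of 203 genes was 0.20, close to its own value. The number of components that rose was 1 without EV replicate 1, 7 without EV replicate 3 and 1 with limma on log2(FPKM + 1). The list did not pass camera (adjusted p = 0.711, and adjusted p = 0.742 with an estimated correlation). It holds activators and inhibitors of the pathway alike, so a change of the pathway need not move it one way. RNA levels of these components do not measure NF-kB activity.

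Enzymes that produce or remove reactive oxygen species also showed no common direction. Because the list mixes both kinds, a change of the balance between them need not move it one way. RNA levels of these genes do not measure reactive oxygen species. Of 22 tested, 4 rose and 5 fell, the same numbers when adjusted over the list alone. The peroxiredoxin gene PRDX2 rose from 95.1 ± 5.13 to 116 ± 5.66 FPKM, GPX3 from 9.55 ± 0.542 to 12.5 ± 0.586 FPKM and SOD1 from 88.1 ± 0.832 to 99.2 ± 2.73 FPKM. MAOA (log2 fold change -0.53), GLRX2 (-0.51) and MSRB2 (-0.56) fell. The median log2 fold change was 0.04 and the mean -0.02, opposite in sign, with a camera adjusted p of 0.850 (adjusted p = 0.869 with an estimated correlation). Of 24 tested targets of NRF2, the oxidative stress regulator, 8 rose and 6 fell (9 and 6 adjusted over the list alone). GSR rose from 68.6 ± 1.05 to 107 ± 0.429 FPKM and PRDX1 from 140 ± 15.9 to 206 ± 10.6 FPKM, while the cystine transporter gene SLC7A11 fell from 103 ± 4.27 to 65.5 ± 6.68 FPKM. FTH1, a ferritin gene with expressed pseudogenes that can share its reads, had a log2 fold change of 0.90. The NRF2 list had a camera adjusted p of 0.122 (adjusted p = 0.614 with an estimated correlation), and 0.0367 without EV replicate 3.

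Transcripts encoded by mitochondrial DNA, the templates on which TEFM acts, were mostly higher. Of the 13 protein genes, 12 rose and none fell, and the count was 12 also when adjusted over the list alone. MT-ND1 rose from 3287 ± 283 to 4795 ± 265 FPKM, MT-ND2 from 4646 ± 405 to 6400.1 ± 147 FPKM, MT-ND3 from 2347 ± 232 to 3196 ± 178 FPKM and MT-ATP6 from 4592 ± 245 to 5909 ± 209 FPKM. MT-CO1, the most abundant transcript in the table, stood at 13523 ± 967 FPKM in EV and 12459 ± 657 FPKM in TEFM (log2 fold change -0.08, edgeR adjusted p = 0.156). Among the next most abundant, MT-CO3 and MT-ND4 rose with log2 fold changes of 0.27 and 0.28, and MT-CO2 with 0.13. The ratio of MT-ND1 to MT-CO1 FPKM was 0.243 ± 0.00361 in EV and 0.385 ± 0.00113 in TEFM, with an exact permutation p of 0.1. All genes of mitochondrial DNA took 6.88% ± 0.553 of counts in EV and 7.64% ± 0.414 in TEFM, ranges that overlap (exact permutation p = 0.2). The list passed camera with the preset correlation (adjusted p = 3.74e-05; adjusted p = 0.478 with an estimated correlation), and not at the preset correlation after quantile normalisation (adjusted p = 0.593). The number that rose was 7 with robust dispersions, 5 with limma without a trend and 2 after quantile normalisation, which fixes the values of top-ranked genes and turned MT-CO2 to -0.06 and MT-ATP6 to -0.02.

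**Figure D2:**
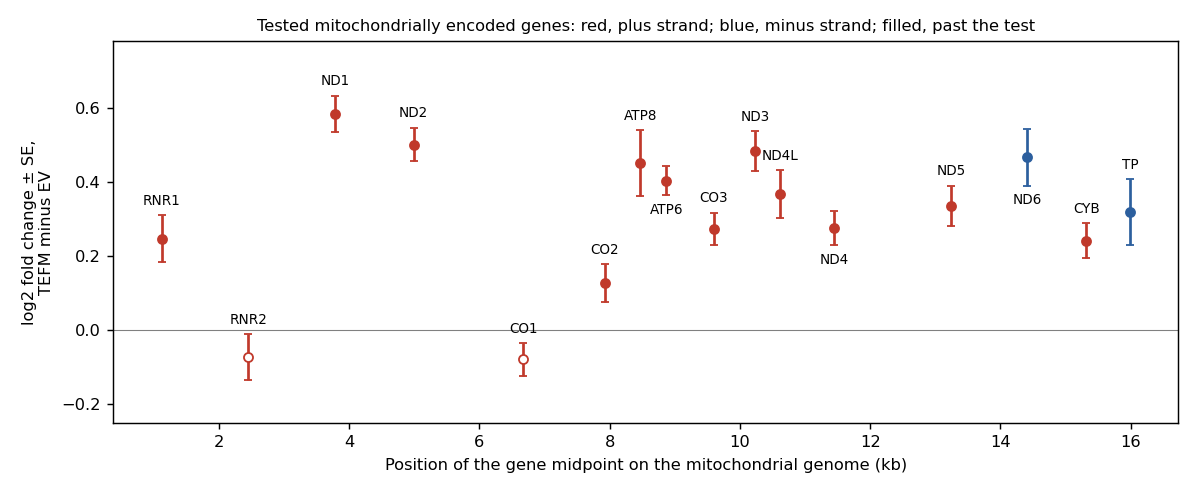
Log2 fold change, TEFM minus EV, with its standard error (vertical axis) against the position of each gene's midpoint on the mitochondrial genome in kb (horizontal axis). Red marks the plus strand, blue the minus strand, and filled points passed the edgeR test. MT-ND1 was highest at 0.58, while MT-CO1 (-0.08) and MT-RNR2 (-0.07) did not pass. MT-TC (0.51, with a standard error of 1.09) was tested, did not pass either and is not drawn.

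Of 56 tested nuclear genes for subunits of oxidative phosphorylation, 35 rose, 2 fell and 19 did not pass; adjusted over the list alone, 36 rose and 2 fell. COX6B1 rose from 45.9 ± 2.08 to 65.1 ± 3.44 FPKM, COX5A from 62.4 ± 3.81 to 84.0 ± 3.15 FPKM and NDUFC2 from 13.8 ± 1.06 to 28.8 ± 1.94 FPKM. NDUFA10 fell from 4.93 ± 0.0625 to 3.14 ± 0.289 FPKM. The list passed camera with the preset correlation (adjusted p = 1.71e-05) but not with an estimated one (adjusted p = 0.290 with an estimated correlation). With limma without a trend, 20 rose. Genes for mitochondrial transcription and mtDNA maintenance moved both ways, 8 of 25 rising and 6 falling, the same numbers when adjusted over the list alone. GRSF1, POLG and TBRG4 rose with log2 fold changes of 0.28, 0.38 and 0.35, whereas MTERF4 (-0.51) and the mitochondrial RNA polymerase gene POLRMT (-0.23) fell. TFAM stood at 17.2 ± 0.545 and 16.8 ± 0.401 FPKM. This list had a camera adjusted p of 0.875 (adjusted p = 0.869 with an estimated correlation), its median log2 fold change being 0.00 and its mean -0.01. Of 45 mitochondrial ribosomal protein genes, 9 rose, MRPL21 (0.48) and MRPS35 (0.25) among them, and 7 fell, with MRPL1 (-0.44) and MRPS10 (-0.29). The numbers were the same when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.619; adjusted p = 0.615 with an estimated correlation).

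The integrated stress response, the programme driven by ATF4, had the median log2 fold change farthest from 0 of all tested lists, but did not pass camera with an estimated correlation. Of 28 members, 25 fell, none rose and 3 did not pass, with the same numbers when adjusted over the list alone. TRIB3, a pseudokinase gene, fell from 50.7 ± 6.81 to 13.4 ± 1.6 FPKM, the glutathione-degrading enzyme gene CHAC1 from 22.9 ± 2.02 to 6.85 ± 0.907 FPKM, and the folate enzyme gene MTHFD2 from 37.3 ± 1.51 to 20.4 ± 1.05 FPKM. ATF4 itself stood at 172 ± 9.31 and 158 ± 4.93 FPKM (edgeR adjusted p = 0.103), and GDF15 at 28.2 ± 3.53 and 28.5 ± 2.18 FPKM. The median log2 fold change of the list was -0.84, with a camera adjusted p of 6.24e-32 at the preset correlation (adjusted p = 0.0911 with an estimated correlation). Of 24 cholesterol synthesis genes, 20 fell, with 1 that rose and 3 that did not pass; the numbers were the same adjusted over the list alone. The sterol-responsive transcription factor gene SREBF2 fell from 43.3 ± 0.975 to 24.7 ± 0.246 FPKM, STARD4 from 20.6 ± 0.872 to 10.2 ± 0.165 FPKM and SQLE from 27.8 ± 1.99 to 12.7 ± 0.384 FPKM. EBP rose by a log2 fold change of 0.20, but the number that rose was 0 without EV replicate 2, EV replicate 3 or TEFM replicate 1, without composition scaling and with limma on log2(FPKM + 1). The camera adjusted p was 1.15e-17 (adjusted p = 0.136 with an estimated correlation).

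**Figure D3:**
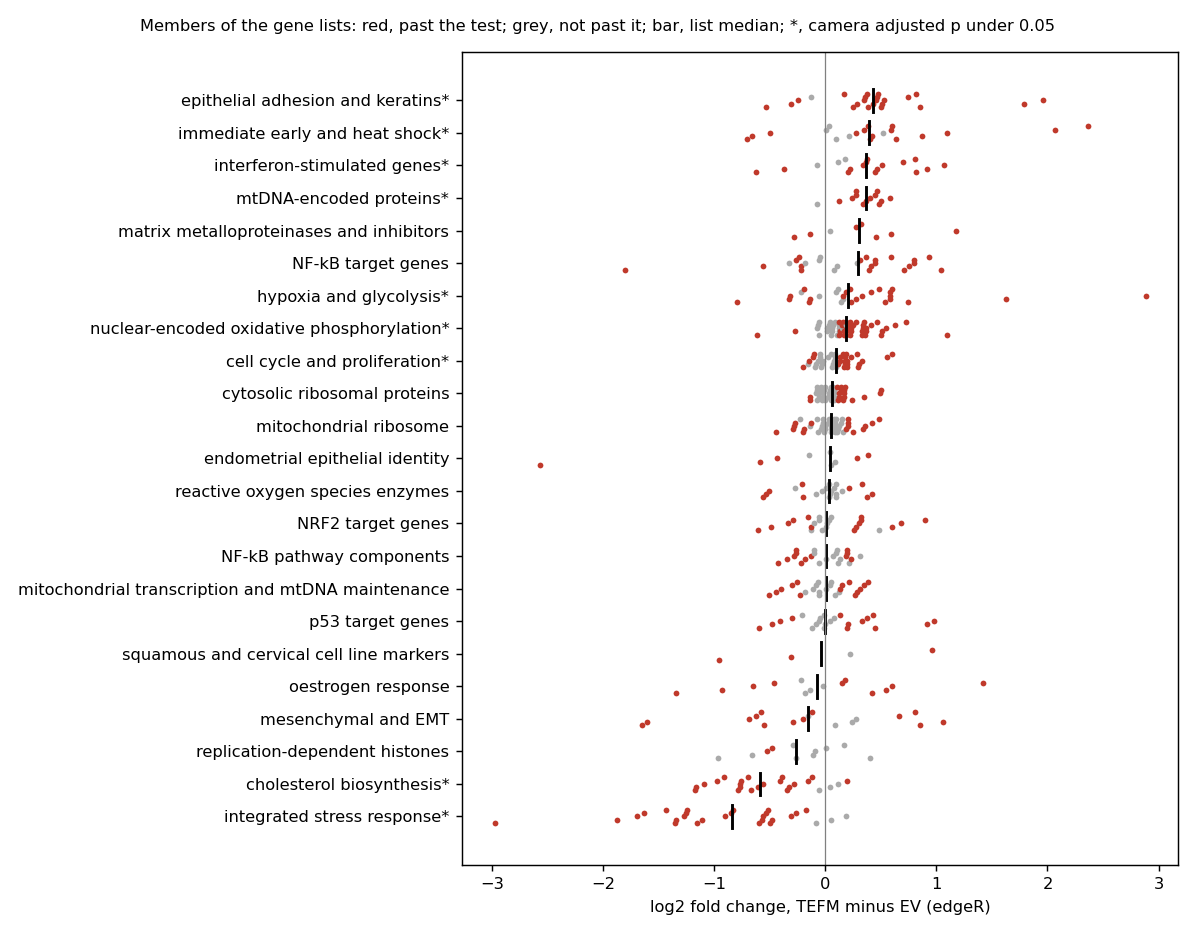
Log2 fold change, TEFM minus EV (horizontal axis), of each tested member of the 23 lists with at least 3 tested genes (vertical axis). Red points passed the edgeR test and grey ones did not, black bars are list medians, and an asterisk marks the 9 lists past camera at the preset correlation, from -0.84 for the integrated stress response to 0.43 for epithelial adhesion.

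Epithelial adhesion and keratin genes rose, 19 of 23 tested, while 3 fell and 1 did not pass, the same numbers when adjusted over the list alone. EPCAM rose from 141 ± 3.64 to 190 ± 1.2 FPKM, KRT8 from 91.9 ± 8.41 to 129 ± 5.61 FPKM, the E-cadherin gene CDH1 from 53.2 ± 0.698 to 66.5 ± 0.920 FPKM and the membrane protease gene ST14 from 32.6 ± 2.11 to 57.2 ± 2.39 FPKM. GRHL2 (log2 fold change -0.53), ESRP1 (-0.31) and TJP1 (-0.25) fell. This was the 1 list that passed camera both ways (adjusted p = 4.42e-13; adjusted p = 0.0421 with an estimated correlation). Of 17 tested mesenchymal genes, 4 rose and 9 fell (5 and 9 adjusted over the list alone). The N-cadherin gene CDH2 fell from 4.11 ± 0.0950 to 1.32 ± 0.0900 FPKM, and TGFBI, TNC and FN1 fell with log2 fold changes of -1.65, -0.58 and -0.62. CD44 rose from 6.33 ± 0.308 to 10.7 ± 0.274 FPKM, and SNAI1 rose by a log2 fold change of 0.85. The mesenchymal list had a camera adjusted p of 0.110 (adjusted p = 0.466 with an estimated correlation), and 0.0408 without a filter on low values. Of 8 matrix protease and inhibitor genes, 5 rose and 2 fell, in both adjustments, including adjusted over the list alone. TIMP2, an inhibitor, rose from 3.19 ± 0.139 to 7.01 ± 0.110 FPKM, MMP15 from 10.9 ± 0.613 to 14.5 ± 2.05 FPKM and MMP14 from 10.3 ± 0.311 to 12.1 ± 0.127 FPKM, with a camera adjusted p of 0.0918 for the list (adjusted p = 0.290 with an estimated correlation) and 0.0408 without a filter on low values.

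In the list of 20 immediate early and heat shock genes, 12 rose, 3 fell and 5 did not pass, or 14 and 3 adjusted over the list alone. DNAJB1 rose from 10.1 ± 0.427 to 21.1 ± 0.480 FPKM and HSP90AA1 from 257 ± 25.1 to 389 ± 6.59 FPKM. JUN fell from 84.5 ± 1.82 to 58.4 ± 3.04 FPKM and DUSP1 from 23.0 ± 1.35 to 14.2 ± 1.78 FPKM, while FOS stood at 62.9 ± 0.549 and 61.6 ± 5.55 FPKM. The camera adjusted p was 4.56e-09 (adjusted p = 0.0911 with an estimated correlation). In the list of hypoxia and glycolysis, 16 of 28 rose, 6 fell and 6 did not pass, or 17 and 6 adjusted over the list alone; 3 fell without EV replicate 3 and after quantile normalisation. NDRG1 rose from 0.317 ± 0.0643 to 2.29 ± 0.484 FPKM, PFKFB3 from 16.8 ± 0.490 to 27.4 ± 1.44 FPKM and LDHA from 90.8 ± 2.54 to 117 ± 3.06 FPKM, whereas VEGFA fell from 12.6 ± 0.685 to 7.07 ± 0.973 FPKM. Its camera adjusted p was 3.14e-07 (adjusted p = 0.0911 with an estimated correlation). Of 18 tested interferon-stimulated genes, 13 rose and 2 fell, the same numbers when adjusted over the list alone. IFIT1 rose from 11 ± 0.195 to 18.8 ± 0.143 FPKM, RSAD2 from 1.98 ± 0.0954 to 4.05 ± 0.683 FPKM, HERC5 by a log2 fold change of 0.44 and OASL by 0.51, and BST2 fell by -0.63. Their camera adjusted p was 0.00132 (adjusted p = 0.136 with an estimated correlation), and 8 of them rose with limma on log2(FPKM + 1).

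Of 40 cell cycle genes, 19 rose and 4 fell (19 and 5 adjusted over the list alone), 14 and 8 without composition scaling, and 11 and 8 with limma on log2(FPKM + 1) or after quantile normalisation. CCND1, the cyclin D1 gene, rose from 147 ± 6.12 to 210 ± 4.87 FPKM, KIF20A from 26.2 ± 0.878 to 38.7 ± 0.866 FPKM and MCM4 from 30.6 ± 1.37 to 36.8 ± 0.732 FPKM, and TYMS fell from 37.1 ± 1.13 to 31.4 ± 1.25 FPKM. Their camera adjusted p was 0.0312 (adjusted p = 0.466 with an estimated correlation). The call ended without composition scaling (adjusted p = 0.0900), at a mean FPKM of at least 5 (0.0917), with limma on log2(FPKM + 1) (0.0775), after quantile normalisation (0.405) and without EV replicate 2 (0.0525). Of 23 p53 targets, 9 rose and 4 fell, the same numbers when adjusted over the list alone. PMAIP1 rose by a log2 fold change of 0.98 and PHLDA3 by 0.91, whereas TNFRSF10B (-0.48) and the cell cycle inhibitor gene CDKN1A (-0.41) fell. The list did not pass camera (adjusted p = 0.619; adjusted p = 0.615 with an estimated correlation). Of 14 oestrogen response genes, 6 rose, such as CA12 (0.60) and ALPG (1.42), and 4 fell, such as NRIP1 (-0.93), SIAH2 (-0.65) and STC2 (-1.34). CA12 is also in the list of hypoxia and glycolysis, and STC2 in that of the integrated stress response. Adjusted over the list alone the numbers were the same, and the camera adjusted p was 0.619 (adjusted p = 0.615 with an estimated correlation).

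Of 44 cytosolic ribosomal protein genes, 15 rose and 2 fell, with the same numbers adjusted over the list alone. Other settings did not keep that balance: 9 rose and 8 fell without composition scaling, 6 and 6 with limma on log2(FPKM + 1), 4 and 16 after quantile normalisation, and 9 and 9 with GC and length offsets, chosen after seeing the data. With 1 library left out, the number that fell went from 0, without TEFM replicate 2, to 4, without TEFM replicate 1. RPS3, RPS25, RPL38 and RPL24 rose with log2 fold changes of 0.49, 0.50, 0.35 and 0.24. The list did not pass camera (adjusted p = 0.0947; adjusted p = 0.593 with an estimated correlation), passed it without EV replicate 3 (0.0367) and without a filter on low values (0.0456), and its median log2 fold change of 0.06 turned to -0.07 after quantile normalisation. Among 11 replication-dependent histone genes, whose transcripts lack poly(A) tails, 2 fell and none rose, in both adjustments, including adjusted over the list alone. These were H1-2 (log2 fold change -0.48) and H2BC11 (-0.52), and H2BC11 no longer passed without EV replicate 2 or without TEFM replicate 3. The list had a camera adjusted p of 0.465 (adjusted p = 0.593 with an estimated correlation).

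Markers of other cell types were sparse. No leukocyte marker reached the expression filter, the highest, FCER1G, being at 0.530 FPKM in EV and 0.567 FPKM in TEFM. Of the fibroblast markers, FBLN1 rose from 9.56 ± 0.307 to 13.9 ± 0.947 FPKM and COL1A1 stood at 1.58 ± 0.0666 and 1.61 ± 0.142 FPKM, and of the endothelial markers EGFL7 fell from 31.4 ± 3.74 to 23.4 ± 2.77 FPKM. Without a filter on low values, 4 of 10 endothelial markers rose and 1 fell, with a median log2 fold change of 0.59, and 4 of 12 fibroblast markers rose. Adjusted over the list alone these calls stayed at 1, 0 and 1 for fibroblast, leukocyte and endothelial markers. Of 4 tested squamous and cervical cell line markers, 1 rose, S100A2 (log2 fold change 0.96), and 2 fell, KRT5 (-0.96) and CDKN2A (-0.30). SFN had a log2 fold change of 0.22 and passed only when adjusted over the list alone, where 2 rose and 2 fell. The camera adjusted p of these markers was 0.465 (adjusted p = 0.614 with an estimated correlation). Of 9 tested genes of endometrial epithelial identity, 2 rose and 3 fell, in both adjustments, including adjusted over the list alone. LGR5, a receptor gene of Wnt signalling, fell from 7.41 ± 0.518 to 1.22 ± 0.116 FPKM and MSX1 from 83.5 ± 7.68 to 59.9 ± 4.32 FPKM, SOX17 rose from 21.6 ± 1.23 to 27.5 ± 2.77 FPKM, and PAX8 stood at 89.3 ± 1.2 and 89.7 ± 1.91 FPKM. The list did not pass camera (adjusted p = 0.150; adjusted p = 0.395 with an estimated correlation), its median log2 fold change of 0.05 and mean of -0.32 differing in sign, and with GC and length offsets, chosen after seeing the data, its adjusted p was 0.0441.

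Genes on the far part of chromosome 11 were higher as a block. Of the 306 tested genes that start at or beyond 70 Mb, 88.9% had a positive log2 fold change, with a median of 0.37 (quartiles 0.20 and 0.56), and 190 were called higher against 8 lower. The 176 genes between 10 and 60 Mb had a median of 0.01, while the 109 genes below 10 Mb had a median of 0.13, with 36 called higher and 14 lower. Within the far block, the bin from 100 to 110 Mb, with a median of 0.21, did not count as shifted. ARRB1, HSPA8, SNORD14E, NDUFC2, ST14, RPS3, RPS25 and UCP2, a mitochondrial carrier gene that rose by a log2 fold change of 0.38, lie in the far block. CCND1, MRPL21, FTH1 and RELA lie between 60 and 70 Mb, where the median of 203 genes was 0.20. At the end of chromosome 2, from 240 Mb, 27 genes had a median of -0.54, and 22 of them fell, MTERF4 among them; NDUFA10 starts just before that block, at 239892450. The largest median shift of a bin was -0.62, over 20 genes of chromosome 13 below 20 Mb, 12 of which fell; its values varied between EV libraries, from 0.05 to 0.40 around the mean of all libraries. Shifted bins also lay on chromosomes 6, 7, 12, 19 and 21, with NRIP1 in that of chromosome 21 from 10 to 20 Mb (median -0.28). Without the genes of the 12 of 280 tested 10 Mb bins whose medians were shifted, the test called 5870 genes, and 31 of 52 oxidative phosphorylation genes rose.

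**Figure D4:**
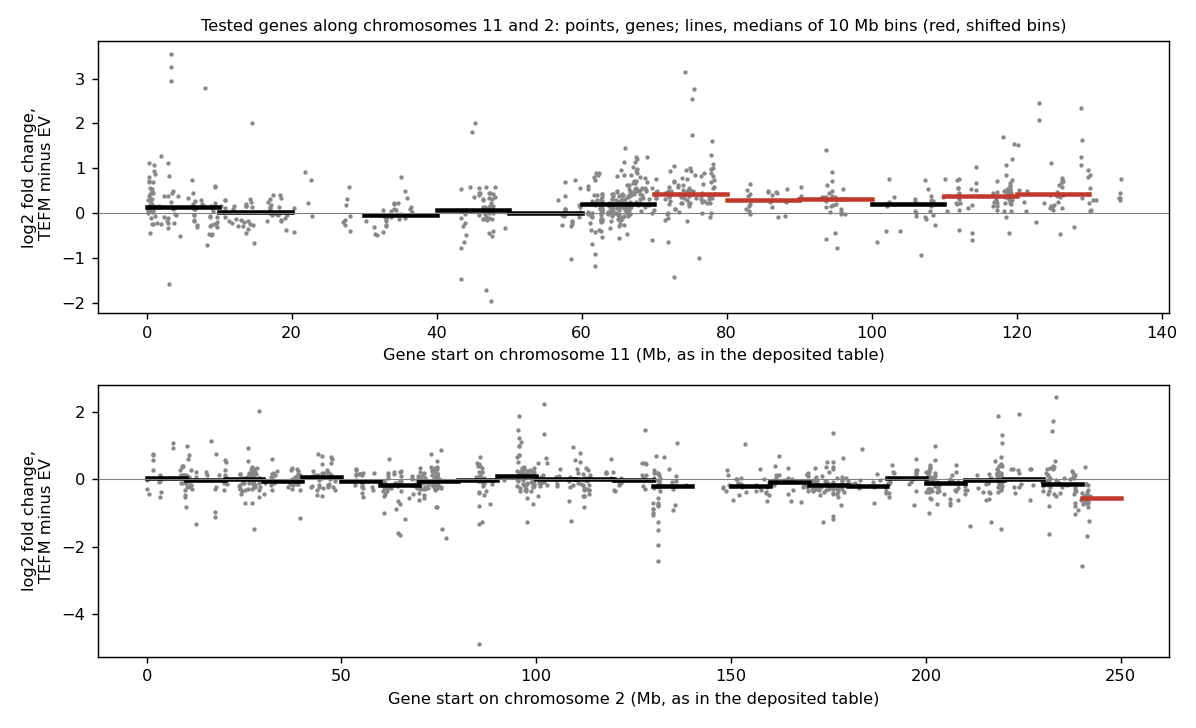
Log2 fold change, TEFM minus EV (vertical axes), of tested genes against their start on chromosome 11 (top) and chromosome 2 (bottom) in Mb, with points for genes and lines for medians of 10 Mb bins, red where shifted. The median was 0.37 over the genes of chromosome 11 from 70 Mb and -0.54 over those of chromosome 2 from 240 Mb.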

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

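GC and length offsets and the removal of shifted segments were chosen after seeing the data; the other alternatives were planned. TEFM stayed past the threshold, with log2 fold changes of 2.20 to 2.55, in each alternative. The number of called genes stayed between 4149 and 6961, and was 5564 with DESeq2, 6051 with the offsets and 5870 without shifted segments. Leaving out each library in turn gave 5157 to 6270 calls and 465 to 538 with an absolute log2 fold change of at least 1. That larger-change count was 495 in the main test, 1409 without a filter on low values, 130 at a mean FPKM of at least 5 (where 2046 genes were higher, since fewer were tested), 256 with limma on log2(FPKM + 1), 252 after quantile normalisation, 250 without a trend and 253 with a robust limma fit; a pseudocount shrinks low genes. With the replicate number as a block, 5935 genes passed. Same-numbered libraries of the 2 groups had deviations correlated at -0.0343, 0.0278 and -0.0227, and not each correlated best with its own number, so the numbers do not pair them. The 9 passing lists became 1 with an estimated correlation and 20 by fry.

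Of 2438 recomputed values of 112 named genes, 2399 kept their direction and side of the threshold, 22 lost and 13 gained a call, and 4 changed sign. MT-CO2 (-0.0574) and MT-ATP6 (-0.0250) turned under quantile normalisation, which fixes the values of top ranks. COL1A1, not called in the main test, was at -0.0628 with the offsets and between -0.0153 and 0.101 with 1 library left out, lowest without TEFM replicate 1; the cause was not tested. Of 528 list tests 480 stayed alike, 18 lost and 18 gained a call, and 12 changed direction, each in a list that passed on neither side. The mitochondrial transcription list turned without a filter on low values (adjusted p = 0.959) and with limma on log2(FPKM + 1), also without a trend or robust (0.952), and with pseudocounts of 0.5 (0.957) and 0.1 (0.966). The p53 (0.988) and endometrial identity (0.731) lists turned at a mean FPKM of at least 5, where fewer genes were tested. The lists of reactive oxygen enzymes (0.764) and cytosolic ribosomal proteins (0.151) turned after quantile normalisation, and reactive oxygen enzymes also with the offsets (0.539). The cause was not tested. Oestrogen response turned without shifted segments (0.842), a setting that takes out NRIP1 (log2 fold change -0.93 in the main test), which lies in a shifted bin of chromosome 21. Camera was not run on the DESeq2 fit. At this depth, simulated 1.2-fold changes in the TEFM versus EV comparison over 14254 genes were recovered for 19 of 50 genes. That share also depends on how few genes the simulation changed, so it does not give the recovery in the data.

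Some list counts moved with the setting. Without EV replicate 1, 9 of the NF-kB targets rose against 13, and 12 interferon-stimulated genes rose and 0 fell; without TEFM replicate 2, 10 rose and 0 fell. Of cell cycle genes, 1 fell without EV replicate 1 and 2 without TEFM replicate 2. Oestrogen response genes that rose numbered 3, and mitochondrial ribosomal genes 5 against 9 that fell, with limma on log2(FPKM + 1). Of reactive oxygen enzymes 6 rose and 6 fell without EV replicate 3.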

Other observations

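The tests of annotation terms, of a copy number difference of the far part of chromosome 11 and of group-wide culture conditions were chosen only after the results were seen. The table pairs its genes with biological process and pathway terms, and 1033 process terms and 289 pathway terms with 15 to 300 tested genes were compared with camera. At the preset correlation 14 process terms were higher and 8 lower, and 8 pathway terms were higher and 4 lower. With an estimated correlation none passed (smallest adjusted p = 0.826 and 0.593 with an estimated correlation). The genes named next were chosen after their values were seen. Fatty acid metabolism was lower, with 19 of 49 genes that fell and 10 that rose (camera adjusted p = 0.0232; adjusted p = 0.593 with an estimated correlation). The desaturase genes FADS2 (73.3 to 31.4 FPKM), FADS1 (35.8 to 18.5 FPKM) and SCD (261 to 140 FPKM) fell, with log2 fold changes of -1.18, -0.91 and -0.86, and so did the elongase gene ELOVL6 (-1.29). CPT1A, which carries fatty acids towards mitochondrial oxidation, rose by a log2 fold change of 0.78 and lies on chromosome 11 between 60 and 70 Mb.

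Under the term on collecting duct acid secretion, 15 of 18 genes rose and 1 fell (camera adjusted p = 0.0232; adjusted p = 0.601 with an estimated correlation). CA2 rose by a log2 fold change of 1.27 and SLC12A7 by 0.32, and of the proton pump subunit genes ATP6V0E1 rose from 34.3 to 55.1 FPKM, ATP6V0D1 from 5.16 to 7.59 FPKM and ATP6V1D from 12.3 to 15.8 FPKM, while ATP6V0A2 fell by a log2 fold change of -0.30. Of 43 genes under the proteasome term, 23 rose and none fell (camera adjusted p = 0.0471; adjusted p = 0.709 with an estimated correlation). PSMD2, PSMD3 and PSMA3 rose with log2 fold changes of 0.33, 0.37 and 0.25. The table's annotation also puts FTSJ3, which encodes no proteasome subunit, under that term. Of 21 genes under the term on the folate one-carbon pool, 11 fell and 1 rose (camera adjusted p = 0.0391; adjusted p = 0.593 with an estimated correlation), with MTR at -0.40 and MTHFD1L at -0.32 beside MTHFD2 and SHMT2, which the integrated stress response list also holds. These counts include NOPCHAP1 (-0.43) and ZBTB25 (-0.27), which fell, and SMCR8 (0.28), which rose, none of them a gene of a folate enzyme. MTHFD1L lies on chromosome 6 in the shifted bin from 150 to 160 Mb, whose median was -0.26.

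The breadth of the difference, 6184 called genes, was weighed first. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one. The highest of the others gave 0 with edgeR, and 10 splits are too few for a share under 0.05. Each other split put libraries of both groups on the same side, so the group difference entered the spread within sides and few calls could arise. The splits therefore decide nothing about chance. GC and length offsets left 80.87% of the calls past the threshold in the same direction, which argues against such bias as the whole cause, although log2 fold changes followed GC content across genes (Spearman rho 0.252; genes are not independent replicates). The 10 Mb bins explained 6.214% of the variance of log2 fold change, against at most 0.411% in 100 shuffles. The 12 shifted bins held 290 of the called genes, so a dosage change shared by genes within such bins is not the whole cause. Bins do not show segments smaller than 10 Mb, or effects of a segment's genes on genes elsewhere. For those, segment copy number stays open. For the far part of chromosome 11, a copy number difference between the cell populations stays open and untested, beside regulation and TEFM: 88.9% of its genes were higher, but the block was picked for that, so the share supports no cause, and DNA was not measured.

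The rise of mitochondrially encoded transcripts was the second pattern. Of the 13 protein genes, 11 were called higher both without composition scaling and with mitochondrial genes left out of the library sizes. Both scalings lie close to the main one, with TMM factors of 0.982 to 1.02 and mitochondrial shares of 6.88% in EV and 7.64% in TEFM. They could hardly end the calls, so they do not decide whether scaling is the cause. After quantile normalisation the list's call ended (camera adjusted p = 0.593), its median going from 0.37 to 0, because that step gives the top ranks, which these genes hold, the same values in each library. The 13 log2 fold changes differed by far more than their standard errors (heterogeneity Q = 168.1 on 12 degrees of freedom), so a single common change of the mitochondrial RNA share does not account for them. If TEFM drove elongation further along the heavy strand, distal genes could rise more. Over the 12 heavy-strand protein genes, the Spearman rho of log2 fold change with position was -0.322 (Pearson r -0.18, two-sided permutation p = 0.311, one-sided permutation p = 0.851 for a rise). Without the 2 farthest genes rho was -0.0303. These values are too close to 0 for 12 genes to decide. The rRNA genes MT-RNR1 (log2 fold change 0.25) and MT-RNR2 (-0.07), which start at 648 and 1671, before MT-ND1, were left out. Both lay below MT-ND1 (0.58), so including them could raise rho. Spread within EV also counts: the list score ranged over 79.9% of the group difference, EV replicate 3 was lowest, and without it 11 genes rose and 1 fell, so a TEFM effect on transcription, processing or stability stays untested.

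The fall of the integrated stress response list was the third pattern. Its score fell by 0.897 between groups, and the widest range within a group was 36.24% of that, which lies between the bounds set for dish-to-dish variation, so that source stays open. A culture condition that differed between the 2 groups as a whole, such as medium age or density, cannot be told apart from TEFM, because it would coincide with the groups. TXNIP (144 to 46.8 FPKM) and ARRDC4 (27.9 to 11.2 FPKM), which respond to glucose, fell, as did the cholesterol list, while the immediate early and heat shock list rose; these 4 were picked after the results were seen, so their moving with the groups supports no cause. An effect of TEFM on mitochondrial stress signalling may equally lower these genes, and no test here separates it from culture.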
